A study of Mus musculus with 4 samples.

How the data were processed

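The data analysed were the deposited count matrices of 4 single-nucleus libraries of mouse pituitary glands, 1 library per labelled group. Per the labels, each library pooled nuclei of 3 glands of UM-HET3 mice, aged 5 or 22 months and labelled male or female. Glands were snap frozen, nuclei were isolated with a 10x Genomics nuclei kit, and libraries were made with the 10x Genomics 3' chemistry with a target of 10000 nuclei each. Per the file headers, the values are counts of unique transcripts made by Cell Ranger 7.0.1, and the genome build is mm10 per the labels. Whether intronic reads were counted is not given in the sources used here. The files hold 32285 genes, of which 32158 had a position in GENCODE M21, and their barcodes had already been selected before they were analysed here. No group has a replicate library.

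Raw counts were used throughout. Barcodes with fewer than 500 genes detected were removed (288, 271, 1411 and 303 in the libraries labelled 5-month males, 5-month females, 22-month males and 22-month females), then those with over 5% mitochondrial counts (56, 74, 118 and 76). Doublets were scored with Scrublet in each library. Its automatic thresholds were 0.161, 0.148, 0.0948 and 0.145, so a single value of 0.146, their median, was used for all libraries after these were seen. It called 11.8%, 12.8%, 16.0% and 12.6% of the barcodes left doublets, and these were removed. The mitochondrial limit was also set without having been planned.

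Nuclei of all libraries were clustered together in scanpy 1.11.5: totals were scaled, logged, and 3000 variable genes chosen, leaving out sex-linked check genes, the 7 hormone genes and mitochondrial genes. A graph of 15 neighbours on 30 principal components was divided by Leiden at resolution 1, which gave 30 clusters. No correction between libraries was made, because group and library are the same thing here. Clusters were named by the class whose markers, fixed before the data were examined, stood highest over the other clusters. The form of the naming score and the clustering settings were settled after the clusters had been seen, and several scores were tried. Names end in -like because they rest on transcripts alone. Clusters with no clear marker stayed unnamed and stayed in the denominators of shares.

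Counts were summed over the nuclei of each class in each library, for classes with at least 30 nuclei in every library. Genes were tested with edgeR 4.0.16 by its quasi-likelihood test, with TMM factors, edgeR's own filter on low counts, and Benjamini-Hochberg adjustment over the genes kept, and a gene passed at an adjusted p under 0.05. Labelled age was tested across the labelled sexes with sex as a term, and labelled sex with age as a term. This leaves 1 residual degree of freedom, the interaction of labelled age and labelled sex, since no group has a replicate library. The spread between libraries therefore rests on very little, and the test counts pools and not mice. The fit also shares spread across genes, with prior degrees of freedom from 6.98 in lactotrope-like to 41.6 in gonadotrope-like nuclei. An adjusted p therefore does not measure how well a difference repeats between pools of the same group. Labelled age was tested in 6 classes and labelled sex in 3 for the comparisons described, and values of further classes stand among the other observations. DESeq2 1.42.0 was run with the same terms. Log2 folds are given with an approximate standard error, the size of the fold over the square root of the test's F statistic. Simulated data with 100 genes changed 2-fold and 100 changed 4-fold were tested in the same way: of the 2-fold changes, 52 of 100 were recovered in stem-like, 61 in somatotrope-like, 65 in lactotrope-like, 42 in corticotrope-like, 52 in melanotrope-like and 41 in gonadotrope-like nuclei, and of the 4-fold changes 87, 98, 93, 81, 99 and 93. Unchanged genes that passed in these runs numbered 9, 9, 3, 0, 5 and 12. Every simulated gene had the same dispersion, the common one of the class's fit, and unchanged genes had equal expression in all libraries. These counts therefore do not show how often unchanged genes pass in the real libraries.

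Between 2 single libraries no test was made. Folds were taken from TMM-scaled log CPM with a prior count of 2, with exact binomial intervals that cover counting error only. Where all counts of a group were 0, the fold is given as a lower limit with a floor of 3 counts per library, and where a group had 1 to 3 counts as the ratio of CPM. Shares of nuclei have Clopper-Pearson 95% intervals, and ratios of shares exact binomial ones. The rule for genes changed alike in both labelled sexes asked for a 2-fold difference and at least 20 counts in the library in which the gene is higher, in each sex.

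The 22 fixed gene lists covered pituitary stem and progenitor factors, the Hippo, Wnt and Notch pathways, NF-kB and inflammation, interferon response, MHC class I and class II, senescence, proliferation, extracellular matrix, unfolded protein response, immediate-early genes, clock, estrogen, steroid and thyroid receptors, hypothalamic receptors, pituitary hormones, p53, ribosomal proteins, mitochondrially encoded genes and the sex-linked check. They name 375 genes, of which 371 are in the files. For each list the members that passed were counted over all genes tested and adjusted over the list alone, and the median fold was set against 10000 random lists of the same size drawn from the 100 genes nearest in expression. As a check, a known shift was added to the real folds, between the libraries labelled males, of random sets of 15 genes in stem-like nuclei. A shift of 0.5 log2 placed 20 of 20 sets above the upper limit of percentile 97.5. With no shift 2 lay above it and 1 below the lower limit. Lists of genes that vary together were not covered by this check.

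The genes named follow a fixed rule. In stem-like nuclei the 10 higher and 10 lower genes with the largest value of the smaller of the 2 within-sex folds among passing genes were named for labelled age, in other classes 4 of each, and for labelled sex 5 of each without the sex-linked check genes. From each list up to 4 passing members were named by smallest p, otherwise up to 2 by highest mean CPM, and each hormone in its own class. For labelled age the ranks were also drawn without the sex-linked check genes, a choice made after the values were seen.

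With 1 library left out, 1 side of the comparison holds a lone library, which is assumed to vary like the others, and the factor is tested with no other term. A call lost or a fold turned in such a fit can come from the library or from the missing term. Alternatives added after the data were seen were Scrublet's own thresholds, class sums thinned to equal depth for the tests, and melanotrope-like nuclei without 1 cluster. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.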

Results

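Single-nucleus RNA sequencing was carried out on pituitary glands of UM-HET3 mice, a genetically heterogeneous stock bred from 4 inbred strains. The labels give 4 libraries, 1 each for 5-month males, 5-month females, 22-month males and 22-month females, and each library pooled the nuclei of 3 glands. No group has a replicate library. The title of the series concerns the aging of pituitary stem cells, so the stem-like nuclei are described first. In the order named, the libraries held 33328821, 35240987, 65773807 and 49262366 counts of unique transcripts (UMIs) in 8343, 7765, 13595 and 8509 barcodes. After filtering, 7059, 6470, 10135 and 7107 nuclei remained, with a median of 3452, 3624.5, 4123 and 4723 counts per nucleus.

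Transcripts of the sex chromosomes did not match the label of 2 libraries. Xist (ENSMUSG00000086503, mm10 chromosome X, 103460366 to 103483254), the RNA that coats the inactive X chromosome of female cells, was counted in 97.4% of the nuclei of the library labelled 22-month males (95% Clopper-Pearson interval 97.1 to 97.7) and in 85.7% of those labelled 22-month females. It was counted in 0.216% of the nuclei labelled 5-month females (interval 0.118 to 0.363) and in 0.0992% of those labelled 5-month males. At least 1 of the 4 Y-linked genes Uty, Eif2s3y, Ddx3y and Kdm5d was counted in 85.6% of the nuclei labelled 5-month males, 84.3% of those labelled 5-month females, 0.207% of those labelled 22-month males and 0.281% of those labelled 22-month females. Summed, these Y-linked genes gave 651, 649, 0.490 and 0.524 CPM (counts scaled to a total of 1e+06) in the same order. The library labelled 5-month females therefore carried Y-linked transcripts and hardly any Xist, and the library labelled 22-month males the reverse. Groups were kept as labelled. The comparison by labelled age is thereby also a comparison of libraries with Xist against libraries with Y-linked transcripts. These data cannot separate labelled age from sex chromosomes in any value of that comparison. The comparison by labelled sex sets libraries with the same sex-chromosome transcripts against each other. If the labels of the 2 libraries that do not match were exchanged, the comparison by labelled age would be that of sex. It would then hold 1 library of each age on each side, and the comparison by labelled sex would be that of age.

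**Figure D1:**
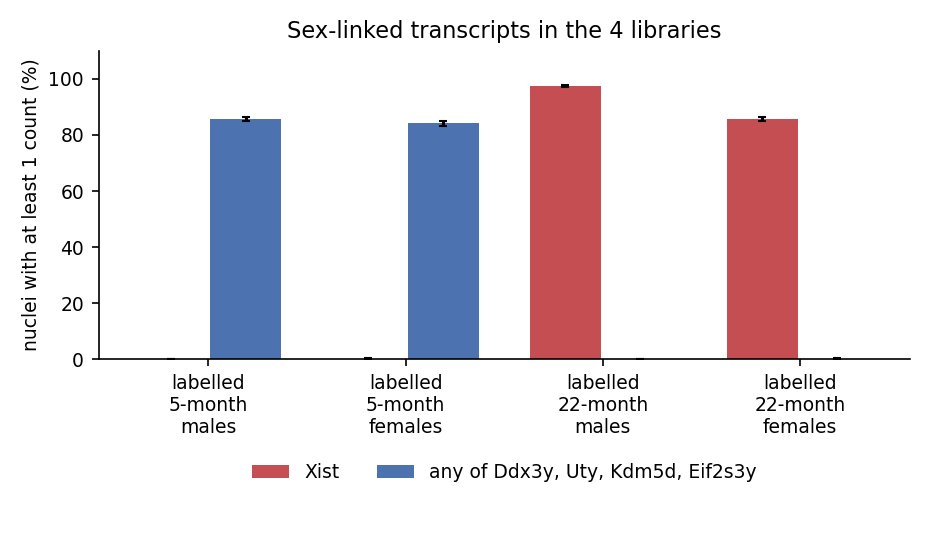
Percent of kept nuclei with at least 1 count of Xist or of any of the 4 Y-linked genes, for each of the 4 labelled libraries, with 95% Clopper-Pearson intervals. Xist was found in 97.4% and 85.7% of the nuclei of the libraries labelled 22-month, and Y-linked transcripts in 85.6% and 84.3% of those labelled 5-month.

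Clustering gave 30 clusters, which were named from marker genes, and 6 hormone-producing and 5 other classes were large enough to sum. Somatotrope-like nuclei, named for growth hormone cells, made up 45.3% and 38.5% of the nuclei in the libraries labelled 5-month males and females, and 22.2% and 27.7% in those labelled 22-month males and females. Their share at labelled 22 months over that at labelled 5 months was 0.490 (95% exact binomial interval 0.464 to 0.517) between the libraries labelled males. Between those labelled females it was 0.719 (0.677 to 0.763). Lactotrope-like nuclei, named for prolactin cells, made up 30.3% and 37.7% against 44.2% and 44.5%, with ratios of 1.46 (1.38 to 1.53) and 1.18 (1.12 to 1.24). Stem-like nuclei made up 4.76% (interval 4.28 to 5.28) and 3.49% (3.06 to 3.97) against 8.34% (7.81 to 8.89) and 3.84% (3.41 to 4.31). Their ratio was 1.75 (1.54 to 1.99) between the libraries labelled males and 1.10 (0.919 to 1.32) between those labelled females, where no difference was detectable at this depth. Gonadotrope-like nuclei, with ratios of 0.652 (0.553 to 0.767) and 0.586 (0.480 to 0.714), and corticotrope-like nuclei, with 0.667 (0.559 to 0.796) and 0.455 (0.338 to 0.608), took lower shares in both libraries labelled 22-month. Melanotrope-like nuclei of the intermediate lobe had ratios of 1.81 (1.61 to 2.05) and 0.789 (0.678 to 0.918), and thyrotrope-like nuclei 0.853 (0.698 to 1.04) and 1.72 (1.37 to 2.17). The thyrotrope-like ratio depended on the clustering. At Leiden resolution 2.0 the thyrotrope-like share was 1.85% and 5.84% in the libraries labelled 5-month and 22-month females. In those labelled males it was 2.61% and 2.58%. These intervals cover counting error only, since each share comes from 1 pool, and no test of shares was made.

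**Figure D2:**
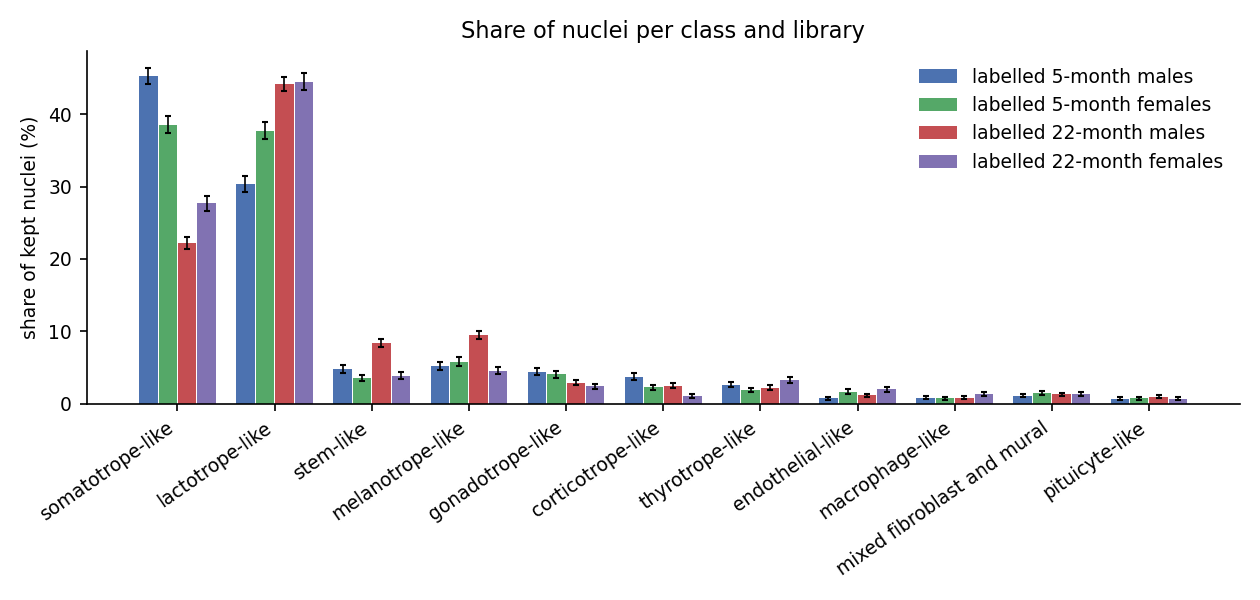
Share of kept nuclei (percent, with 95% Clopper-Pearson intervals) in each class for the 4 labelled libraries. Somatotrope-like nuclei took 45.3% and 38.5% in the libraries labelled 5-month and 22.2% and 27.7% in those labelled 22-month.

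Lactotrope-like, somatotrope-like and gonadotrope-like nuclei also separated by labelled age within their class. Of the lactotrope-like clusters, the largest, with 4585 nuclei, came mainly from the libraries labelled 5-month, and the others mainly from 1 of the libraries labelled 22-month, up to 96.0% from males and 96.4% from females. The somatotrope-like and gonadotrope-like nuclei split in the same manner into clusters led by 1 labelled age, and 97.8% of the nuclei of 1 somatotrope-like cluster came from the library labelled 22-month males. Corticotrope-like nuclei formed 1 cluster with both labelled ages, and the larger melanotrope-like and thyrotrope-like clusters held both as well, while all 75 nuclei of the other thyrotrope-like cluster came from the library labelled 22-month females. The stem-like nuclei fell into 2 clusters.

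In stem-like nuclei, defined by Sox2, Sox9, Aldh1a2 and other progenitor markers, the question was which genes differ with labelled age. The 4 class sums came from 336, 226, 845 and 273 nuclei. Among the genes higher in both libraries labelled 22-month were Luzp2 by a log2 fold of 3.33 ± 0.36 (standard error; adjusted p 4.64e-07), Grm7, a glutamate receptor, by 2.91 ± 0.33 (7.65e-07), Sgcz by 2.92 ± 0.41 (1.85e-05) and the transcription factor Dach2 by 2.90 ± 0.38 (9.54e-06). Gal, which encodes the neuropeptide galanin (ENSMUSG00000024907, chromosome 19, 3409915 to 3414544), had 0 and 3 counts in the libraries labelled 5-month males and females and 186 and 61 in those labelled 22-month (adjusted p 2.24e-07). This was at least 19.0-fold higher between the libraries labelled males, taking a floor of 3 counts per library, and 13.7-fold higher between those labelled females (log2 interval 2.17 to 6.10). Gal reached 77.6 and 64.6 CPM in these nuclei and 82.7 and 93.6 CPM in the lactotrope-like nuclei of the same libraries, and its counts do not separate RNA made in stem-like nuclei from free RNA. Lower in both libraries labelled 22-month were the carboxypeptidase Cpa6 (-4.40 ± 0.33, 2.34e-10), the iron-binding lipocalin Lcn2 (-3.00 ± 0.28, 2.59e-08), Tmem196 (-2.70 ± 0.30, 6.52e-07), the ephrin receptor Ephb1 (-2.62 ± 0.28, 3.46e-07) and Cd109 (-2.85 ± 0.36, 4.57e-06).

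By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 436 of 10099 genes passed in stem-like nuclei, 214 higher and 222 lower in the libraries labelled 22-month. Autosomes gave 198 higher and 209 lower of 9728 tested, and the X chromosome 16 higher and 9 lower of 347. All 4 Y-linked genes were lower, Uty by at least 188-fold and 84.3-fold between the libraries labelled males and females, and Xist was higher by 7.78 ± 0.28. Tsix, which overlaps Xist on the other strand, was higher by 2.52 ± 0.22. With the libraries labelled 5-month males, 5-month females, 22-month males and 22-month females left out in turn, 72, 114, 435 and 242 genes passed. There were 40 genes, 20 higher and 20 lower, that passed in the same direction with any 1 library left out, among them Gal, Luzp2, Grm7, Sgcz, Dach2, Cpa6, Lcn2, Tmem196, Ephb1 and Cd109. DESeq2 passed 69 genes, and edgeR without the sex term passed 209.

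Other genes that ranked highest lost their calls when 1 library was left out. Csmd1, a large transmembrane protein gene, was higher by 3.01 ± 0.29 (adjusted p 5.35e-08), but its CPM was 57.1, 1.57, 409 and 45.5 in the order of the libraries above. Its adjusted p was 0.0724, 0.430 and 0.587 without the libraries labelled 5-month males, 5-month females and 22-month males. Mdga2, a neuronal adhesion molecule, was higher by 2.40 ± 0.22 (1.55e-08), and lost its call without the library labelled 5-month males (adjusted p 0.0922). The X-linked Il1rapl2 was 15.6-fold and 14.2-fold higher between the libraries labelled males and females, from 1 count in each library labelled 5-month, and Reln, an extracellular glycoprotein, was 9.05-fold and at least 4.06-fold higher, at 24.6 and 19.1 CPM against 742 and 1447 in lactotrope-like nuclei. Without the library labelled 5-month females neither passed (adjusted p 0.0553 and 0.0899); Il1rapl2 also did not pass without 5-month males (0.0991), nor Reln without 22-month males (0.0881). The tight junction gene Cldn10 (-2.73 ± 0.40), the phospholipase receptor gene Pla2r1 (-3.10 ± 0.53) and the cystine transporter gene Slc7a11 (-2.52 ± 0.42) were lower, and each lost its call without the library labelled 5-month males (adjusted p 0.302, 0.478 and 0.0926). Saxo2 and Cacna1e, a calcium channel gene, passed from low counts (adjusted p 0.0195 and 0.00156); Saxo2 lost its call with any 1 library left out and Cacna1e without 5-month females or 22-month females (0.194 and 0.277).

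Some regulators of the progenitor state were lower in the stem-like nuclei of the libraries labelled 22-month. Of 16 listed pituitary stem and progenitor factors, 11 were tested. The Notch effector Hes1 (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796) fell by 1.78 ± 0.25 on the log2 scale (adjusted p 2.32e-05), with 423, 232, 75.1 and 121 CPM in the order of the libraries above. The LIM homeobox gene Lhx3 fell by 1.29 ± 0.21 (0.000189). Over all genes 3 members of the list passed lower and 0 higher; adjusted over the list alone 5 were lower and 1 higher. The median log2 fold of the list was -0.41 and -0.48 between the libraries labelled males and females, at percentiles 0.01 and 0.05 of random lists matched on expression. In the Notch list, 9 genes were tested and 2 were lower, Hes1 and Hey1 (-1.21 ± 0.29, 0.00962), 3 lower adjusted over the list alone, with medians of -0.35 and -0.55 (percentiles 0.46 and 0.08). Lhx3 passed with any 1 library left out. Hes1 did not pass without the library labelled 5-month males (-1.28, adjusted p 0.0883). Hey1 failed without any 1 of 3 libraries (0.395, 0.0553 and 0.0796 without 5-month males, 5-month females and 22-month males).

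In the estrogen list, 3 of 7 tested members passed higher in the stem-like nuclei of the libraries labelled 22-month and 0 lower, and 4 were higher adjusted over the list alone. Those 3 were Gal, Esr1 and Prl, and Prl is a transcript of lactotropes that was counted in every class. The estrogen receptor gene Esr1 was higher by 1.49 ± 0.24 (adjusted p 0.000164), with 32.6 and 48.6 CPM against 91.8 and 138; without the library labelled 5-month males it did not pass (0.208). The list's median was 1.36 and 1.04, above all random lists in both pairs. Random lists were matched on expression alone, so this placing does not separate RNA made in stem-like nuclei from free RNA of lactotropes. The list of steroid and thyroid receptors had 9 tested members and passed Esr1 alone, with 4 higher adjusted over the list alone and medians of 0.21 and 0.38.

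Immediate-early genes, which are induced within minutes of a stimulus, were lower in the libraries labelled 22-month, mostly through 1 library. All 5 tested members passed lower, also adjusted over the list alone, with Junb at -2.88 ± 0.34 (adjusted p 1.37e-06), Jun at -2.62 ± 0.37, Ier2 at -2.74 ± 0.38 and Jund at -1.69 ± 0.26. The list's median was -2.92 between the libraries labelled males and -0.76 between those labelled females. Without the library labelled 5-month males these 4 no longer passed (log2 fold of -0.49 for Junb and adjusted p 0.377, 0.695 and 0.888 for Jun, Ier2 and Jund), and Jund did not pass without the library labelled 22-month females (0.121). The 16 listed genes summed to 1178 CPM in the stem-like nuclei labelled 5-month males, against 209, 175 and 139 in the other 3 libraries, in the order above.

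The remaining lists gave few calls in stem-like nuclei. Over all genes, 1 gene passed lower in each of the NF-kB list (Lcn2, of 9 tested; medians -0.30 and -0.30), the MHC class I list (H2-D1, -1.20 ± 0.22, of 9; medians -0.43 and -0.22), the senescence list (Igfbp5, -0.96 ± 0.17, of 5; medians 0.04 and -0.03) and the clock list (Per3, -0.75 ± 0.20, of 16; medians -0.34 and 0.01). The interferon list had 1 gene higher of 16, Herc6 (adjusted p 0.0488; medians 0.14 and 0.24). Adjusted over the list alone the counts were unchanged but for 2 lower in the MHC class I list. Without the library labelled 5-month males, H2-D1, Igfbp5, Per3 and Herc6 all failed to pass (adjusted p 0.321, 0.352, 0.568 and 0.101). Igfbp5 (0.486) and Herc6 (0.575) also failed without 5-month females, Igfbp5 (0.0967) without 22-month males and Herc6 (0.354) without 22-month females, and Per3 failed with any 1 library left out. No member passed by edgeR in the Hippo (11 tested, medians -0.21 and 0.21), Wnt (10, 0.08 and 0.05), proliferation (3, 0.02 and 0.16), extracellular matrix (6, -0.44 and -0.06), unfolded protein (18, 0.14 and -0.13), hypothalamic receptor (3, 0.19 and 0.06), p53 (7, -0.25 and 0.19), ribosomal protein (26, 0.33 and -0.42) and mitochondrial (13, 0.29 and -0.57) lists, nor adjusted over the list alone. Tead1, the main DNA-binding partner of YAP in these nuclei by CPM, stood at -0.04 ± 0.18 and Tcf7l2 at -0.02 ± 0.17. The MHC class II list had 2 tested members, Cd74 and H2-DMa, and neither passed. Of the hormone genes, 6 were tested and 1 was higher and 3 were lower (1 and 4 adjusted over the list alone); Prl counts in these nuclei were 10706, 4837, 69954 and 24749 CPM, and Gh counts 55954, 29871, 31037 and 16006 CPM, in cells that are not known to make either hormone.

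In lactotrope-like nuclei, many more genes differed between the labelled ages than in stem-like nuclei, with sums of 7291056 to 21829004 counts. Prl (ENSMUSG00000021342, chromosome 13, 27057570 to 27065205), the hormone of these cells, was higher in the libraries labelled 22-month by 1.61 ± 0.36 (adjusted p 0.0168), at 38828 and 18472 CPM of plain totals against 90340 and 56829. It rose as well in classes that do not make it, in macrophage-like nuclei from 11727 and 7598 to 85643 and 29468 CPM, so the rise is not told apart from free Prl RNA. The kinase gene Pak7 was higher by 8.42 ± 0.20 (9.03e-07), Reln by 8.55 ± 0.29 (2e-06), and Crhbp, which encodes a binding protein for corticotropin-releasing hormone, by at least 330-fold between the libraries labelled males. The collagen gene Col4a3 was lower by -5.20 ± 0.18 (2.46e-06), Megf10 by -5.64 ± 0.27 (1.06e-05), the netrin gene Ntn4 by -5.50 ± 0.35 and the receptor-modifying gene Ramp1 by -5.28 ± 0.36. Estrogen-responsive genes were higher: 6 of 9 tested passed higher and 0 lower, the same adjusted over the list alone, with Greb1 at 1.57 ± 0.12 (0.00014), the progesterone receptor gene Pgr at 2.32 ± 0.18 (0.000132) and Gal at 4.37 ± 0.35 (0.000148). Drd2, the dopamine receptor through which the hypothalamus restrains prolactin, fell by 0.68 ± 0.11 (0.00491).

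Other groups moved in lactotrope-like nuclei as well. Interferon response genes fell: 8 of 23 passed lower and 0 higher, also adjusted over the list alone, with Parp14 at -1.27 ± 0.18, Ddx60 at -1.09 ± 0.18 and Oasl2 at -1.10 ± 0.19, and medians of -0.44 and -0.69 (percentiles 0.22 and 0.05). Of 15 NF-kB and inflammatory genes, 6 were higher and 2 lower (7 and 2 adjusted over the list alone), with the interleukin-6 receptor gene Il6ra at 2.77 ± 0.31 and the inhibitor gene Nfkbia at 0.98 ± 0.17. Of 13 mitochondrially encoded genes, 8 were higher and 0 lower (10 and 0 adjusted over the list alone), with mt-Nd3 at 1.12 ± 0.15, and the median percent of mitochondrial counts over all kept nuclei moved the same way, at 0.184, 0.277, 0.459 and 0.342 in the order of the libraries above. The growth factor receptor gene Igf1r (1.67 ± 0.14), the stress sensor gene Ern1 (1.58 ± 0.14) and the collagen gene Col1a2 (1.97 ± 0.18) were higher. The Wnt effector Tcf7l2 was higher by 5.69 ± 0.21, from 0.509 and 3.06 CPM to 16.9 and 173, and Yap1 by 2.73 ± 0.48, both highest in the library labelled 22-month females.

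In total 3689 of 16388 genes passed by edgeR in lactotrope-like nuclei, 1914 higher and 1775 lower, of which 1825 and 1715 lay on autosomes. With the libraries labelled 5-month males, 5-month females, 22-month males and 22-month females left out in turn, 914, 599, 2151 and 1024 passed, and 476 genes, 263 higher and 213 lower, passed with any 1 left out. These included Pak7, Reln, Crhbp, Col4a3, Megf10, Ramp1, Ntn4, Greb1, Pgr, Gal, Ern1 and Col1a2. They did not include Prl (adjusted p 0.113, 0.307, 0.174 and 0.0880 in the same order) or Drd2 (0.0962, 0.163, 0.0687 and 0.0513), and Tcf7l2 did not pass without either library labelled 5-month (0.145 and 0.118), nor Yap1 without these (0.179 and 0.197) or without 22-month females (0.0946). Ddx60 (0.129, 0.860, 0.470 and 0.0969) and mt-Nd3 (0.472, 0.0622, 0.0777 and 0.592) passed in none of these fits, Oasl2 only without 22-month females, and Parp14 not without 5-month females (0.166) or 22-month males (0.0632). Nfkbia failed without 5-month females (0.0836) or 22-month females (0.0576), and Igf1r without 5-month males (0.0507). DESeq2 passed 1859 genes, and edgeR without the sex term 1945.

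**Figure D3:**
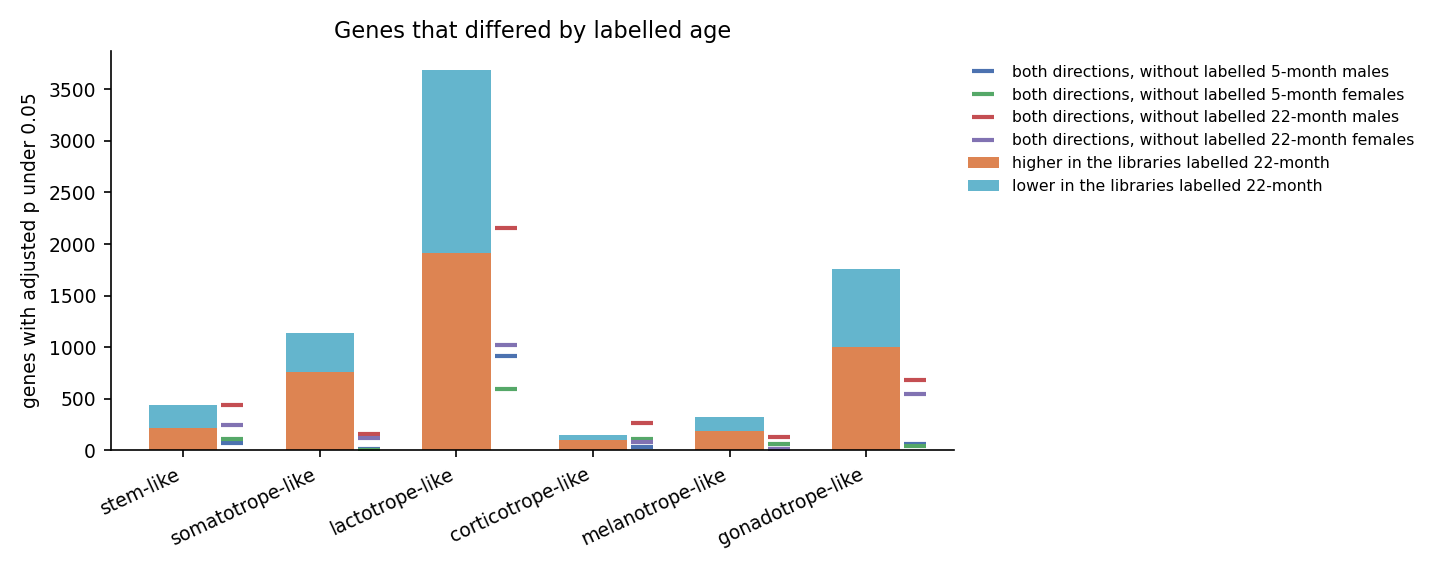
Number of genes that passed edgeR's test of labelled age (adjusted p under 0.05) in each of 6 classes, stacked as higher and lower in the libraries labelled 22-month, with marks for the count with each library left out in turn. Counts run from 145 in corticotrope-like to 3689 in lactotrope-like nuclei, and fell as low as 0 in somatotrope-like nuclei without the library labelled 5-month females.

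In somatotrope-like nuclei the growth hormone gene Gh (ENSMUSG00000020713, chromosome 11, 106300271 to 106301865) did not pass, at a log2 fold of -0.64 ± 0.28 (adjusted p 0.197), with 224950, 163767, 142082 and 103105 CPM of plain totals. Transcripts abundant in the lactotrope-like nuclei labelled 22-month were counted more often here too: Pak7 by 7.17 ± 0.24 (1.72e-06), Reln by 5.91 ± 0.22 (2.92e-06), Crhbp by at least 90.8-fold and 42.0-fold between the libraries labelled males and females, and the X-linked Frmpd4 by 7.09 ± 0.26. Prl, a transcript of lactotropes, reached 6908, 3882, 50664 and 20757 CPM in somatotrope-like nuclei, so these counts do not separate RNA made here from free RNA of lactotropes. Ptchd4 was lower by -4.23 ± 0.25 (4.18e-05) and the axon guidance gene Ntng1 by -2.73 ± 0.21. The hedgehog effector Gli1 had 92 and 73 counts against 2 and 0. Of 12 tested estrogen-responsive genes, 7 were higher, Prl included, and 1 was lower (8 and 1 adjusted over the list alone), with Gal at 4.70 ± 0.27, Greb1 at 2.68 ± 0.23, Pgr at 1.74 ± 0.25, Nrip1 at 0.85 ± 0.13 and Esr1 at 0.64 ± 0.12 (adjusted p 0.0190). The list's medians of 0.95 and 1.68 lay above all random lists, which were not matched on free RNA of lactotropes. Clock genes gave 1 higher and 2 lower of 19, with Per3 at -0.96 ± 0.13 and medians of -0.30 and -0.29 (percentiles 0.13 and 0.22). The antigen presentation genes B2m (-1.68 ± 0.22) and H2-D1 (-0.75 ± 0.16) were lower, and 4 of 13 mitochondrially encoded genes were higher (7 adjusted over the list alone), along with the higher mitochondrial percent of all nuclei in the libraries labelled 22-month.

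By edgeR 1141 of 15598 genes passed in somatotrope-like nuclei, 759 higher and 382 lower. Without the library labelled 5-month females 0 genes passed by edgeR, with 1815 at an unadjusted p under 0.05, and without 5-month males, 22-month males and 22-month females 14, 162 and 120 passed, so every call named for this class is lost without the library labelled 5-month females. DESeq2 on all 4 libraries passed 556, and edgeR without the sex term 112.

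In gonadotrope-like nuclei the gonadotropin genes were lower in the libraries labelled 22-month. Fshb (ENSMUSG00000027120, chromosome 2, 107056140 to 107059656), the subunit specific to follicle-stimulating hormone, fell by 2.29 ± 0.24 on the log2 scale (adjusted p 3.85e-10), with 3916 and 4207 CPM of plain totals against 538 and 1076. Lhb, the luteinizing hormone subunit, fell by 1.86 ± 0.24 (5.22e-08) and the shared subunit Cga by 0.87 ± 0.26 (0.0176), while Gnrhr, the receptor for gonadotropin-releasing hormone, was higher by 0.74 ± 0.20 (0.00867). The sarcoglycan gene Sgcd was higher by 6.85 ± 0.31 (6.65e-22), the cadherin gene Cdh11 by 5.69 ± 0.28 (1.91e-20) and the tachykinin receptor gene Tacr1 by at least 19.7-fold and 18.9-fold. The dopamine receptor gene Drd4 was at least 11.3-fold and 5.69-fold lower. Of 10 tested estrogen-responsive genes, 6 were higher, Prl included, and 0 lower (6 and 1 adjusted over the list alone), with Greb1 at 3.28 ± 0.24 and Pgr at 2.53 ± 0.22. Clock genes fell: 6 of 17 were lower and 0 higher (8 and 0 adjusted over the list alone), with Per3 at -1.24 ± 0.19, Dbp at -1.15 ± 0.22, Per1 at -1.76 ± 0.39 and Per2 at -2.00 ± 0.45, and medians of -0.50 and -0.80 (percentiles 0.04 and 0). Immediate-early genes were lower as well, 5 of 8 tested (6 adjusted over the list alone), and summed to 3900 CPM in the library labelled 5-month males against 259, 247 and 197 in the others; Per1 and Per2 also respond to stimuli. Of 26 ribosomal protein genes, 10 were lower (14 adjusted over the list alone), and 3 of 6 extracellular matrix genes were higher.

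Here 1758 of 11950 genes passed, 1001 higher and 757 lower. Without the libraries labelled 5-month males, 5-month females, 22-month males and 22-month females the counts were 65, 46, 679 and 547, and 35 genes, Sgcd, Cdh11, Tacr1 and Gal among them, passed with any 1 left out. Fshb and Lhb passed without either library labelled 22-month but not without either labelled 5-month (adjusted p 0.208 and 0.237 for Fshb, 0.155 and 0.346 for Lhb), and Cga and Gnrhr passed in none of these fits (adjusted p from 0.0893 to 0.610 for Cga and from 0.151 to 0.572 for Gnrhr). Greb1 did not pass without 5-month females (0.0627), nor Pgr (0.214 and 0.206) and Per3 (0.210 and 0.206) without 5-month males or 5-month females. Drd4 (0.246 and 0.182) and Dbp (0.187 and 0.224) also failed without these 2, Per2 failed without all but 22-month males (0.175, 0.397 and 0.0759), and Per1 failed in every such fit (0.433, 0.130, 0.116 and 0.0597 in the order of the libraries). DESeq2 passed 349, and edgeR without the sex term 250.

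**Figure D4:**
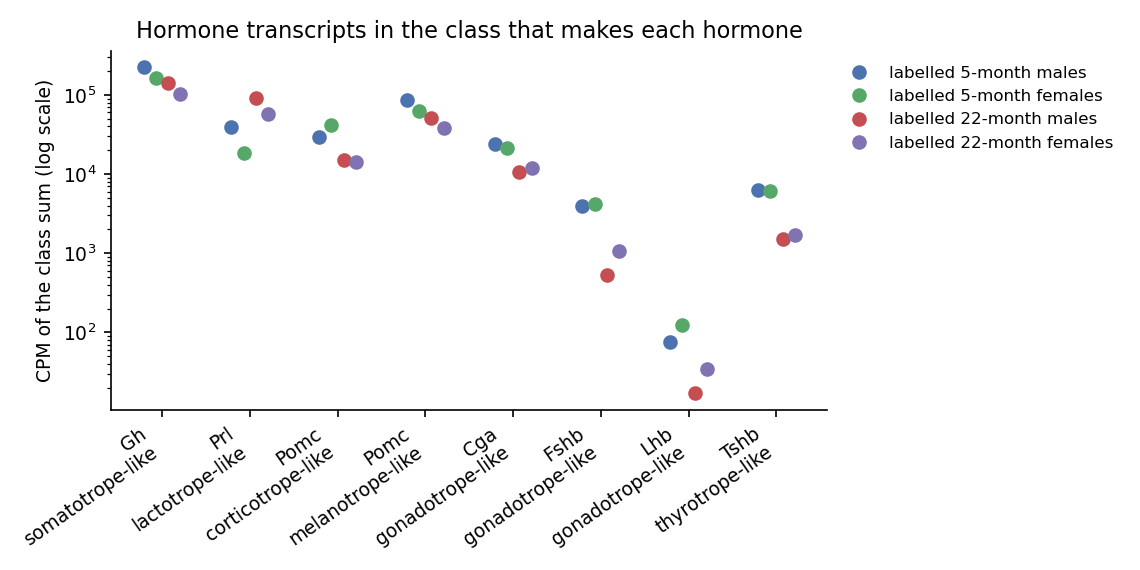
Hormone transcripts in the class named for each hormone, as CPM of the class total on a log axis, each point 1 labelled library. Fshb stood at 3916 and 4207 in the libraries labelled 5-month and at 538 and 1076 in those labelled 22-month, and Prl at 38828 and 18472 against 90340 and 56829.

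Pomc (ENSMUSG00000020660, chromosome 12, 3954951 to 3960642), the precursor of corticotropin and melanocyte-stimulating hormone, fell by 1.23 ± 0.14 on the log2 scale in corticotrope-like nuclei (adjusted p 5.13e-06) and stood at -0.69 ± 0.22 (0.0856) in melanotrope-like nuclei, where it did not pass. Gal was at least 16.5-fold and 15.1-fold higher in corticotrope-like and 32.8-fold and 27.8-fold higher in melanotrope-like nuclei, from 0 to 3 counts in the libraries labelled 5-month, at 53.7 and 78.0 and at 41.8 and 44.0 CPM in those labelled 22-month; here too free RNA is not told apart. Greb1 (2.95 ± 0.41) and Ecel1 (3.45 ± 0.37) were higher in melanotrope-like nuclei, and Car10 (3.34 ± 0.36) in corticotrope-like nuclei. Of the estrogen list, 4 of 8 were higher and 1 lower in corticotrope-like (the same adjusted over the list alone) and, again counting Prl, 4 of 11 were higher and 2 lower in melanotrope-like nuclei (5 and 2 adjusted over the list alone). Immediate-early genes were lower, 7 of 10 tested in corticotrope-like (9 adjusted over the list alone) and 11 of 12 in melanotrope-like nuclei (12 adjusted over the list alone), with Junb at -2.58 ± 0.25 and -3.85 ± 0.40. Summed, the immediate-early genes reached 4864 CPM in the melanotrope-like nuclei labelled 5-month males against 541, 360 and 408 in the other libraries, and 281 of the 298 nuclei of the smaller melanotrope-like cluster came from that library.

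In corticotrope-like nuclei 145 of 9598 genes passed, 104 higher and 41 lower, and in melanotrope-like nuclei 324 of 12395, 184 higher and 140 lower. Without the libraries labelled 5-month males, 5-month females, 22-month males and 22-month females 34, 106, 270 and 86 genes passed in the former and 12, 61, 134 and 15 in the latter, and 20 and 8 genes passed with any 1 left out, Gal in both classes and Car10 in corticotrope-like nuclei. Without 5-month females Pomc no longer passed in corticotrope-like nuclei (adjusted p 0.110), and without 5-month males neither Junb there (0.927) nor Ecel1 and Greb1 in melanotrope-like nuclei (0.347 and 0.195) did; these last 2 also did not pass without 22-month females (0.323 and 0.250), nor Greb1 without 5-month females (0.117), nor Junb in melanotrope-like nuclei without either library labelled 22-month (0.0543 and 0.438). DESeq2 passed 17 and 39 genes in the 2 classes, edgeR without the sex term 18 and 8, and 46 passed in melanotrope-like nuclei without the smaller of their clusters.

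**Figure D5:**
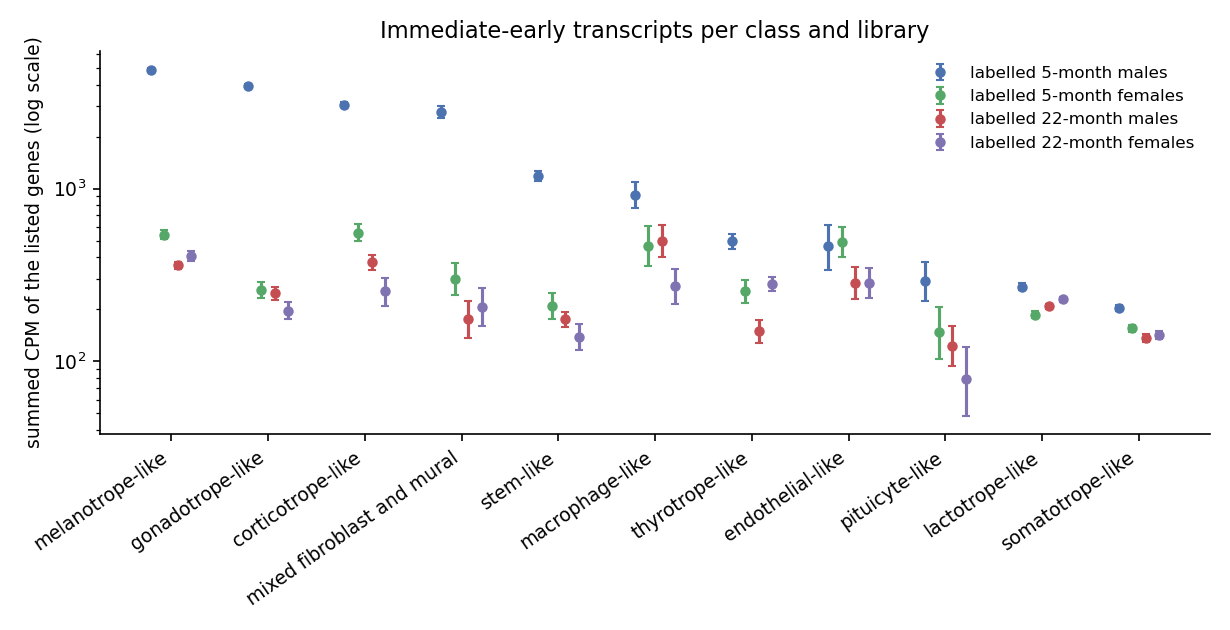
Summed CPM of the 16 listed immediate-early genes in each class, on a log axis, in the 4 labelled libraries with 95% counting intervals. In melanotrope-like nuclei the library labelled 5-month males stood at 4864 and the highest other library at 541.

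A size rule without a test counted genes at least 2-fold different between the labelled ages in the same direction in both labelled sexes, with at least 20 counts in the higher library of each pair. It gave 166 genes in stem-like, 477 in somatotrope-like, 1387 in lactotrope-like, 71 in corticotrope-like, 82 in melanotrope-like and 489 in gonadotrope-like nuclei. Genes 2-fold different in opposite directions numbered 7, 24, 16, 7, 18 and 7. In counts simulated with no gene changed, 0 to 4 genes met the rule. Such counts do not show how many genes differ between single pools for reasons other than labelled age. Applied to labelled sex in place of labelled age, the rule gave 27 genes in stem-like, 121 in somatotrope-like and 105 in lactotrope-like nuclei, with 4, 27 and 21 in opposite directions.

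By labelled sex, stem-like nuclei had 53 of 10099 genes past the threshold, 21 higher in the libraries labelled males and 32 higher in those labelled females. None of the 6 sex-linked check genes was among them, and these directions rest on the labels doubted above. Csmd1 was higher in the libraries labelled males by 3.34 ± 0.29 (adjusted p 2.64e-08) and the scaffold gene Grip1 by 1.89 ± 0.22 (7.42e-06). The noncoding RNA Snhg11 (ENSMUSG00000044349, chromosome 2, 158375638 to 158386145) was higher in those labelled females, at -2.55 ± 0.19 (1.29e-09), with 122 and 135 CPM in the libraries labelled males and 804 and 721 in those labelled females. The acyltransferase gene Mogat1 (-2.01 ± 0.31) and the endocytic receptor gene Lrp2 (-1.99 ± 0.34) were also higher in those labelled females. Immediate-early genes were higher in those labelled males, 3 of 5 tested (5 adjusted over the list alone), with Junb at 2.67 ± 0.39. This came mostly through the library labelled 5-month males. The listed genes summed to 1178 CPM there and 209 in the library labelled 5-month females, against 175 and 139 in those labelled 22-month males and females. Without the libraries labelled 5-month males, 5-month females, 22-month males and 22-month females 28, 1, 48 and 0 genes passed, the last with 406 at an unadjusted p under 0.05, so no call held in all of these fits. Snhg11 failed only without 22-month females (adjusted p 0.0799), Junb without either library labelled 5-month (1 and 0.818) or without 22-month females (1), Csmd1 passed only without 5-month males, and Grip1 failed without either library labelled females (0.317 and 0.451). DESeq2 on all libraries passed 9 genes, and edgeR without the age term 1. The fits with a library left out lack the age term too. Apart from the immediate-early genes, a call lost there therefore need not have rested on that library.

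In somatotrope-like nuclei 107 of 15598 genes passed by labelled sex, 20 higher in the libraries labelled males and 87 higher in those labelled females. Galntl6 (2.79 ± 0.15, adjusted p 0.000531), Rgs6 (2.18 ± 0.28) and Palld (1.91 ± 0.17) were higher in those labelled males, and the potassium channel genes Kcnq3 (-2.95 ± 0.17, 0.000548) and Kcnt2 (-2.35 ± 0.19) in those labelled females. Tcf7l2 (-1.54 ± 0.18) and Znrf3 (-0.89 ± 0.13), 2 of 17 tested Wnt genes (3 adjusted over the list alone), and Esr1 (-0.72 ± 0.12, 0.0461) were higher in those labelled females. Ribosomal protein genes gave 0 calls over all genes and 10 higher in those labelled males adjusted over the list alone. Without the library labelled 5-month males 2 genes passed, Galntl6 among them (adjusted p 0.0424), and without each of the other libraries 0 passed by edgeR, with 805, 837 and 431 at an unadjusted p under 0.05 without 5-month females, 22-month males and 22-month females. On all 4 libraries DESeq2 passed 131, and edgeR without the age term 0, with 483 at an unadjusted p under 0.05. The fits with a library left out lack the age term too, so they do not show that the calls rest on single libraries.

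In lactotrope-like nuclei 83 of 16388 genes passed by labelled sex, 8 higher in the libraries labelled males and 75 in those labelled females. The semaphorin gene Sema3c (2.69 ± 0.39, adjusted p 0.0380), Rims1 (1.95 ± 0.23), Dok6 (1.71 ± 0.27) and Klhl1 (1.14 ± 0.12) were higher in those labelled males. Tcf7l2 (-3.29 ± 0.19, 0.00195), the serine protease inhibitor gene Serpinb3b (-4.34 ± 0.42), the fatty acid transporter gene Cd36 (-4.44 ± 0.55) and the interferon-induced Ddx60 (-1.42 ± 0.18) were higher in those labelled females. Prl did not pass, at 0.85 ± 0.36 (0.431). The immunoglobulin gene Igha, a transcript of plasma cells, had 0 counts in both libraries labelled males and 29 and 24 in those labelled females. With any 1 library left out the fit had no age term, so labelled age entered the comparison by labelled sex. These fits therefore do not show whether the calls rest on single libraries. Without 22-month females Tcf7l2 turned to 1.55 in such a fit, though it was higher in the library labelled females at each labelled age. DESeq2 on all 4 libraries passed 113, and edgeR without the age term 0, with 184 at an unadjusted p under 0.05. With all libraries and the age term kept, edgeR passed 2 with DESeq2's size factors, 1 at Leiden 2.0 and 1 with sums thinned. In each of these fits 12 of 13 named genes no longer passed, and 0 turned. It passed 341 with no filter and 158 with at least 1000 genes per nucleus. With doublets kept it passed 99, with hormone genes removed 88 and with Scrublet's own thresholds 74.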

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

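The share of melanotrope-like nuclei was the result marked because it moved in opposite directions in the 2 labelled sexes, with both intervals away from 1. It was 1.81 times as high in the library labelled 22-month males as in the one labelled 5-month males (interval 1.61 to 2.05), and 0.789 times between the libraries labelled females (0.678 to 0.918). The difference between the sexes was not tested, since each share comes from 1 pool. The intervals cover counting error only, and 2 of the 4 libraries carry sex-chromosome transcripts that do not match their label. No test of a cause was chosen for this result.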

How the results depend on the processing

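No paired analysis was possible because each library is a separate pool and nothing links a library of one age to a library of the other. Intervals cover counting error only, and without both libraries with a doubted label 1 library per age remains, which leaves no residual degree of freedom. In all, 50 counts of genes kept within 1.5 times of their value and 77 moved. Of the counts of genes changed alike in both sexes 7 stayed and 11 moved. Of the tests of named genes 2993 stayed as they were, 1188 were weaker and 6 turned. Of the folds within a labelled sex 1949 stayed and 157 moved. Of the shares of classes 211 stayed within their counting interval and 85 left it. Share ratios were followed only in the 6 classes tested for age, without thyrotrope-like nuclei. There 51 stayed within their counting interval while 9 left it. For every result that moved the cause was not tested.

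Genes by labelled age in stem-like nuclei numbered 436, and 69 by DESeq2, 209 without the sex term, 667 at Leiden 2.0 and 72 to 435 with 1 library left out. In somatotrope-like nuclei there were 1141, and 2370 with no filter, 556 by DESeq2, 112 without the sex term, 649 with Scrublet's own thresholds and 0 to 162 with 1 left out. Lactotrope-like nuclei had 3689, and 1859 by DESeq2, 1945 without the sex term and 599 to 2151 with 1 left out. Corticotrope-like nuclei had 145, and 263 with no filter, 17 by DESeq2, 18 without the sex term, 251 with at least 1000 genes per nucleus, 271 at Leiden 2.0, 359 with doublets kept, 33 with Scrublet's own thresholds and 34 to 270 with 1 left out. Melanotrope-like nuclei had 324, and 158 with no filter, 39 by DESeq2, 8 without the sex term, 498 with doublets kept, 131 with Scrublet's own thresholds, 46 without the smaller cluster and 12 to 134 with 1 left out. Gonadotrope-like nuclei had 1758, and 349 by DESeq2, 250 without the sex term, 901 with doublets kept and 46 to 679 with 1 left out.

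By labelled sex, stem-like nuclei had 53, and 99 with no filter, 9 by DESeq2, 1 without the age term, 123 with hormone genes removed, 97 at Leiden 2.0, 10 with doublets kept, 126 with Scrublet's own thresholds and 0 to 48 with 1 left out. Somatotrope-like nuclei had 107, and 734 with no filter, 0 without the age term, 49 with hormone genes removed, 50 with doublets kept, 57 with Scrublet's own thresholds, 165 with sums thinned and 0 to 2 with 1 left out. Lactotrope-like nuclei had 83, and 2 with DESeq2's size factors, 341 with no filter, 0 without the age term, 158 with at least 1000 genes, 1 at Leiden 2.0, 1 with sums thinned and 0 to 0 with 1 left out. With 1 library left out the log2 fold of Ier2 ran from -4.61 to 0.0664 in melanotrope-like and from -5.40 to 0.51 in gonadotrope-like nuclei by age and from -0.26 to 2.88 in stem-like nuclei by sex, turning without 5-month males. By sex, Adamts19 ran from -8.90 to 2.23 in somatotrope-like nuclei, and Mir9-3hg from -9.61 to 0.92 and Tcf7l2 from -7.40 to 1.55 in lactotrope-like nuclei, turning without 22-month females. These fits have no age term, so such a turn can come from the difference between labelled ages.

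Genes changed alike in both sexes numbered 519, 1320, 2697, 277, 381 and 1312 at 1.5-fold in stem-like, somatotrope-like, lactotrope-like, corticotrope-like, melanotrope-like and gonadotrope-like nuclei, and 84, 307, 27, 44 and 287 with at least 50 counts in all but lactotrope-like nuclei. The lactotrope-like share ratio was 1.54 between libraries labelled males at Leiden 2.0 and 1.54 with each library clustered alone, and 1.31, 1.33 and 1.29 between those labelled females at Leiden 2.0, with doublets kept and clustered alone. The somatotrope-like ratio was 0.565 and 0.666 clustered alone and 0.763 at Leiden 2.0 for females, and the stem-like ratio 2.19 for males with at least 1000 genes. With the 7 hormone genes left out of totals the median log2 fold of all genes lay more than 0.1 below 0 in 3 classes, at -0.17 and -0.17 in lactotrope-like, -0.11 and -0.11 in somatotrope-like and -0.11 and -0.17 in gonadotrope-like nuclei.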

Other observations

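In thyrotrope-like nuclei, Tshb, the subunit specific to thyroid-stimulating hormone, stood at 6206 and 6035 CPM in the libraries labelled 5-month and at 1492 and 1711 in those labelled 22-month, and 75 of the 227 nuclei labelled 22-month females formed a cluster of that library alone. There 343 of 10234 genes passed edgeR's test by labelled age, 188 higher and 155 lower, and of 9 tested estrogen-responsive genes 5 were higher and 1 lower, with medians of 0.82 and 1.32. By labelled age 22 genes passed in endothelial-like and 53 in pituicyte-like nuclei. By labelled sex 446 genes passed in gonadotrope-like and 259 in melanotrope-like nuclei, counts that were not tested with a library left out or by another method.

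The tests of mixed nuclei, of depth, of male nuclei and of Xist in every class, and the gonadotrope-like test of free RNA, were chosen only after the result was seen. The others were written first, though plasma cell and list totals of whole libraries and Xist by class had been seen.

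The sex-linked transcripts did not match the labels of 2 libraries. Mixing of nuclei of both sexes was argued against, since at most 0.281% of the nuclei of a library carried transcripts of the rarer state. An exchange of the labels of the 5-month female and 22-month male libraries may explain it. Plasma cell transcripts and collagen transcripts differed in the direction written first in 3 of 4 comparisons, short of the 4 set. Plasma cell transcripts met both of theirs, but their totals had been seen before. Collagen transcripts were lower in the library labelled 5-month females than in that of males (600 against 855 CPM). Between the libraries labelled 22-month their intervals overlapped (430 to 570 and 510 to 652). The tally therefore decides little, and the question stays open. A wrong sex with a right age met 2 of 8 comparisons, and fewer than 4 had been set as the outcome against it. The comparisons of both explanations set single pools side by side, and plasma cell transcripts were highest in 1 pool (9.28 CPM in the library labelled 5-month females). This explanation therefore stays open too. If the labels were exchanged, the comparison by labelled age would be that of sex and the comparison by labelled sex that of age.

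In the library labelled 22-month females, 22.3% of the lactotrope-like nuclei carried no Xist count, against 1.72% in that labelled 22-month males. Depth could not account for it, since at equal depth the shares lay 25.3 points apart. Only 0.284% of these nuclei had a Y-linked count, which argues against male nuclei, and at most 3.40% of stem-like or melanotrope-like nuclei lacked Xist, the higher being melanotrope-like nuclei, against 0.105% in the other library. Nuclei without Xist were also more frequent in this library among thyrotrope-like (26.9% against 0%), unnamed (14.9% against 1.11%), corticotrope-like (11.1% against 0.398%) and gonadotrope-like nuclei (8.33% against 0%). They were less frequent among endothelial-like (2.86% against 11.2%) and alike among somatotrope-like nuclei (4.67% against 4.63%). In CPM, Xist was lower in this library in every class named so far in this paragraph, also in endothelial-like (1599 against 1741) and somatotrope-like nuclei (1831 against 2093). It was higher in macrophage-like (2059 against 1794), fibroblast and mural (1961 against 1715) and pituicyte-like nuclei (2481 against 2387), so not every class had less Xist. Genes that escape X inactivation stood at 1.10 times (interval 1.05 to 1.15) the CPM of nuclei with Xist, which argues against loss of the inactive X, and the cause stays open.

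Immediate-early genes were highest in the library labelled 5-month males. They were highest there beyond counting intervals in 9 of the 10 classes other than melanotrope-like, but by unequal amounts. The ratio to the highest other library was 1.18 in lactotrope-like and 1.31 in somatotrope-like nuclei. It was 9.24 in fibroblast and mural nuclei and higher still in gonadotrope-like nuclei. In lactotrope-like and somatotrope-like nuclei the excess (41.7 and 47.6 CPM) lay below what free RNA from melanotrope-like nuclei would carry (216 and 180). The count of 9 therefore does not show a like shift in all classes. Handling of that library as a whole may still be the cause, and the stress of a single pool or time of death would look the same. Free RNA from melanotrope-like nuclei was not ruled out, since its bound was passed in only 3 of 10 classes, though corticotrope-like nuclei make Pomc themselves and could hardly pass it. In gonadotrope-like nuclei the excess was 20.3 times what free RNA would carry, which argues against free RNA there; it was 2484 CPM against 255 in the fibroblast and mural nuclei and 969 against 305 in stem-like nuclei.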
